A study of Mus musculus with 23 samples.

How the data were processed

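Genomic DNA from the left ventricle of the heart and from the spleen of male C57Bl/6 mice was sheared and enriched for methylated CpG sites with MethylMiner, a kit that captures DNA bound by a methyl-CpG binding protein. The captured fragments were sequenced. Per the labels, mice received 1 of 3 diets: a control diet lacking resistant starch, a diet rich in resistant starch (high fibre), or 100 mM magnesium acetate in the drinking water. Feeding began 3 weeks before minipump surgery and lasted to the end of the study. The labels do not state whether every library of a group came from a separate mouse, so p-values measure the spread between these libraries.

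The deposited values are counts: raw reads per gene window in each library, in 1 table for heart and 1 for spleen, without normalization or pooling of replicates. Each table holds 41388 windows of 3 kb at transcription start sites. The processing notes name bcl2fastq 2.19.1.403, BWA 0.7.10, featureCounts 1.5.1 and edgeR 3.16.5, with genome build GRCm38. How a window is centred and how reads with several alignments, duplicate reads or reads in several windows were counted is not stated. No unenriched input library was used, so counts compare libraries and give no absolute methylation level. A window with more reads than the same window in another library held more captured DNA, at equal scaling. Capture efficiency and DNA copy number also enter these counts, so more reads need not mean more methylation.

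Windows were checked before use. All values were whole numbers. Of 33499 windows above 100 reads, 0 shared their counts with another window in all libraries. A symbol occurred more than once for 137 symbols. Gene positions came from a RefSeq table of build GRCm38 patch 6, matched by symbol for 30507 windows and through a synonym for 1588, 77.5% of all windows. Across 20153 protein-coding windows, total count and number of RefSeq transcripts had a Spearman rho of 0.302; windows are not independent replicates.

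Library totals ranged from 4.12 to 8.60 M (mega) counts in 11 heart libraries and from 4.36 to 9.87 M in 12 spleen libraries. Outside the 5 largest windows, totals were 2.41 to 4.40 M in heart and 1.85 to 3.85 M in spleen. The median count per window lay between 26 and 70 in heart and between 13 and 29 in spleen. Counting error and differences between samples are both part of the tests.

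Groups were tissue by diet, 6 in all. The main test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM scaling factors, filterByExpr at a minimum count of 10, and Benjamini-Hochberg adjustment at 5% across windows. Log2 fold changes used a prior count of 2. The 3 diets of a tissue shared 1 estimate of spread. Heart against spleen on the control diet, and the differences between tissues in each diet effect, came from 1 fit over all 23 libraries. Normalised read counts (CPM, reads per M reads of a library after scaling) are given as mean ± SD over the n libraries of a group. Scaling was done within a tissue for diet comparisons and over both tissues for the others, so the CPM of a gene differs between those sections. Per-library levels in the closing section were scaled within a tissue over all windows. TMM sets the bulk of windows near 0, so changes are relative to that bulk.

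For each comparison the named genes were the 10 higher and 10 lower windows with the smallest p past the threshold, or the 5 higher and 5 lower with the smallest p where none passed. For heart against spleen the 10 per direction had the largest absolute change among windows past the threshold and above the median abundance. A fixed set of genes was named in every diet comparison, among them Ffar2, Ffar3, Hcar2, Slc16a1, Acss2, Dnmt1, Dnmt3a, Tet2, Hdac4, Egr1, Foxp3, Nppa, Agtr1a, Ren1 and Tgfb1. For each gene list past its threshold the 4 members with the smallest p were added. Symbols of the forms Gm plus number, Rik, Mir, AC and BC were skipped for naming. Duplicated symbols and placeholders without a symbol were also skipped, a step added to the rule after the tables were opened. Some genes chosen by these rules are not reported here. A few other genes are named in the text outside this rule and were picked after their values were seen. They are the other list members in the observations, Gm10800, the windows beside Tbc1d2b, and windows that deviated alike in both tissues with their neighbours.

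The 20 gene lists hold 656 genes, of which 639 were found: cardiomyocyte, B cell, T and NK cell, myeloid, erythroid, fibroblast, endothelial, smooth muscle and pericyte, short-chain fatty acid sensing, transport and acetate metabolism, DNA methylation and one-carbon, histone acetylation, cardiac stress, fibrosis and inflammation, blood pressure and renin-angiotensin, circadian clock, regulatory and helper T cell, imprinted, germline, housekeeping, Hox clusters, and MHC and interferon response. Lists with at least 5 tested members were tested with camera of limma 3.58.1 on log2 CPM, with a preset correlation between genes of 0.01 and again with the correlation estimated. Fry served as a further set test. Adjustment was over the lists of a comparison.

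Library composition was described by total counts, the share of windows without reads, the share of counts in the top 1% of windows, and an enrichment measure. That measure is the mean log2 CPM of 92 imprinted and germline genes, whose promoters often carry methylation, minus that of 36 housekeeping genes, whose CpG islands usually lack it. Groups were compared with exact two-sided permutation tests. Shared direction of both diet effects was described by the Pearson correlation across windows, set beside 100 simulations of unchanged groups that share their controls. Whether replicate or title numbers pair samples was checked by correlating the deviations of same-numbered libraries. The median r was 0.0987 over 10 heart pairs, 0.0530 over 12 spleen pairs and 0.0020 over 11 pairs across tissues. Over pairs with different numbers it was -0.018, -0.007 and 0.004. Single pairs across tissues ran from -0.44 to 0.37, so these medians cannot decide whether same-numbered libraries share a mouse. No pairing was used, and the main fit over both tissues treated same-numbered libraries as independent.

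The comparisons, tests, lists, the naming rule and the following alternatives were fixed before the data were examined: RLE scaling, library totals, cyclic loess, DESeq2 1.42.0, voom, voom with quality weights, no filter, a filter at a mean of 30 reads, a replicate block, a covariate for title numbers from 16, 1 surrogate variable from sva 3.50.0, a fit to only the compared diets, autosomal windows, a prior count of 0.5, tissue contrasts within the other diets, and each library left out in turn. Alternatives added after the data were seen were the enrichment measure as a covariate, a covariate for title numbers from 11, and the heart fit without acetate replicate 1. The tests of the Gm10800 share and of the Tbc1d2b region were also added then.

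The procedure was tested on simulated data in which 200 windows were given folds of 1.5, 2 or 3. Each window was drawn independently, without differences shared across the windows of a library. Reads were not realigned and sites within windows were not analysed here.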

Results

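Captured methylated DNA was counted over 41388 gene start windows in 23 libraries from mouse heart (left ventricle) and spleen. Heart held 4 libraries of mice on the control diet, 4 on high fibre and 3 on acetate. Spleen held 4 libraries of each diet. Total counts ran from 4.12 to 8.60 M (mega) in heart and from 4.36 to 9.87 M in spleen. Reads piled up in a few windows: Gm10800 (ENSMUSG00000075014), a predicted gene in satellite-like repeat sequence, took 33.1% of all heart counts and 54.5% of all spleen counts.

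The composition of the heart libraries moved with the high fibre diet. Gm10800 took 19.05% ± 1.70 (SD, n = 4) of counts in high fibre heart, 42.3% ± 5.80 (n = 4) in control heart and 33.8% ± 10.5 (n = 3) in acetate heart. In spleen the shares were 55.8% ± 2.84 on control, 55.8% ± 4.70 on high fibre and 51.9% ± 2.69 on acetate (n = 4 each). The top 1% of windows took 28.8% ± 1.82 of counts in high fibre heart and 53.1% ± 5.91 in control heart. The enrichment measure, imprinted and germline genes against housekeeping genes on the log2 scale, was 1.02 ± 0.03 in high fibre heart, 1.17 ± 0.09 in control heart and 1.20 ± 0.21 in acetate heart. Windows without reads made up 11.6% ± 0.333 in high fibre heart and 12.98% ± 0.505 in control heart, with totals of 4.79 ± 0.707 and 6.97 ± 1.13 M counts. Each of these 4 planned measures separated all high fibre from all control heart libraries, with an exact permutation p of 0.0286, the smallest that the design allows. Of 28 planned exact tests 9 had p under 0.05 and 0 passed adjustment, the smallest adjusted p being 0.0889. The fall of the Gm10800 share on high fibre was larger in heart than in spleen by 23.1 points (difference -23.1, permutation p = 0.0147 over 4900 permutations). The corresponding difference for acetate was -4.47 points, with a permutation p of 0.599. Diet labels were permuted within each tissue, so these p-values test for no diet effect in either tissue. They do not test whether the effects are equal in both.

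**Figure D1:**
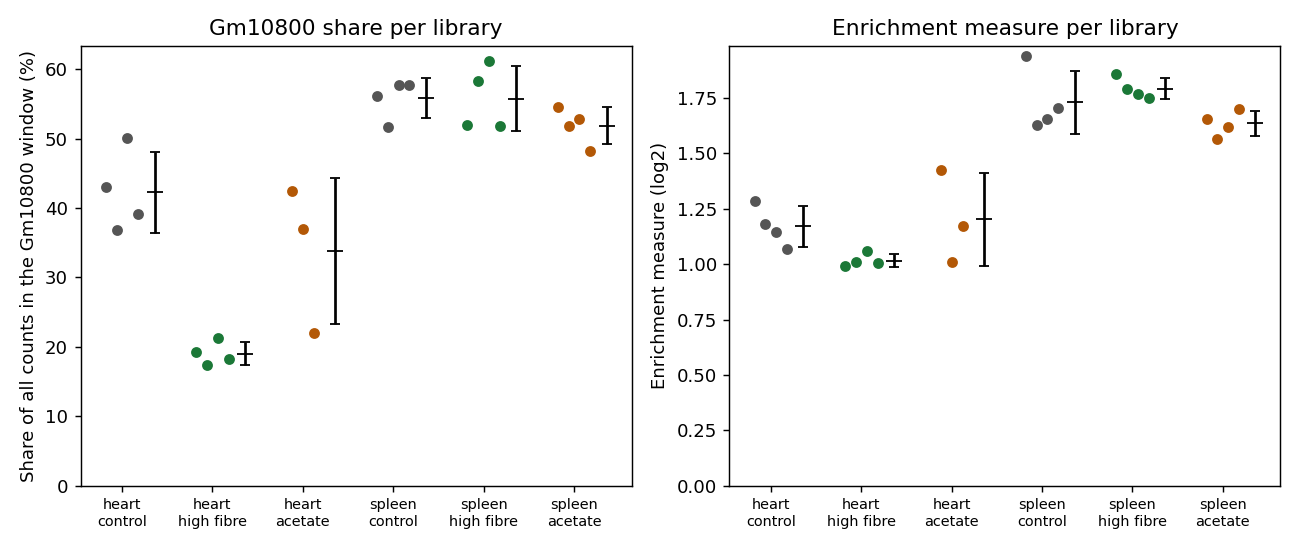
Share of counts in Gm10800 (percent) and the enrichment measure (log2) of each of the 23 libraries by tissue and diet, with group mean ± SD. High fibre heart libraries lie at 17.3 to 21.3% of counts in Gm10800, below all control heart libraries, which lie at 36.8 to 50.05%.

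The first comparison asks whether the high fibre diet goes with other methylation in the heart. Captured DNA fell on high fibre at Ehmt2, which encodes a histone H3 lysine 9 methyltransferase, from 95.3 ± 7.64 to 49.1 ± 4.62 CPM (n = 4 each, 1.94-fold lower). It also fell at Osm, the cytokine oncostatin M, from 41.9 ± 6.87 to 21.7 ± 1.94 CPM, and at Hps6, a subunit of a complex that builds lysosome-related organelles, from 39.3 ± 2.48 to 21.8 ± 1.60 CPM. It rose at Col3a1, the collagen III chain of fibrous tissue, from 20.1 ± 3.43 to 41.4 ± 6.59 CPM. Dsc2, a desmosomal cadherin that joins heart muscle cells, rose from 15.1 ± 2.11 to 26.6 ± 1.43 CPM. In each of these genes every high fibre library lay on the same side of every control library. The same libraries had the lower Gm10800 share and enrichment measure given above.

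In numbers, edgeR called 8786 of 33562 tested windows (26.2%), 4227 higher and 4559 lower on high fibre, with 13872 windows at an unadjusted p under 0.05. Ehmt2 (ENSMUSG00000013787, GRCm38 chromosome 17, 34898463 to 34914073) had a log2 fold change of -0.96 (SE 0.15, adjusted p = 0.00274). Hps6 (ENSMUSG00000074811) had -0.85 (SE 0.13, adjusted p = 0.00247) and Osm (ENSMUSG00000058755) -0.95 (SE 0.15, adjusted p = 0.00274). Also lower were Ggt6, a gamma-glutamyltransferase family member (-0.89), Cryaa, a lens chaperone (-0.90), and Aanat, the enzyme that acetylates serotonin on the way to melatonin (-0.70). Rpl36-ps1, Rpl37rt and n-R5s84, ribosomal pseudogene or retrogene copies and a ribosomal RNA gene, had -0.995, -0.90 and -0.80. Among the higher genes Col3a1 (ENSMUSG00000026043) had 1.04 (SE 0.17, adjusted p = 0.00274). Rasa1, which switches off Ras, rose by 0.93, Phip, which binds an insulin receptor substrate, by 0.76, Orc4 of the replication origin complex by 0.98, and Spata5, an ATPase, by 0.82. Olfr1454, an olfactory receptor, rose by 1.88, Sval2 by 1.41 and RP24-128K11.1 by 1.70. With library totals as the scale, the genes named here as higher stayed higher and past the threshold. That scale moved the median of all windows from 0.02 to 0.71, so it is no test of the higher genes. With 1 surrogate variable Col3a1 (0.53, adjusted p = 0.0789), Dsc2 (0.54, adjusted p = 0.124), Orc4, Spata5, Olfr1454, Sval2, RP24-128K11.1 and n-R5s84 lost their calls, while cyclic loess and the enrichment covariate ended none of the calls named here. The lower genes lost their call with library totals, with Ehmt2 at -0.26, Osm at -0.24, Hps6 at -0.15 and Aanat turned to 0.0011.

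Genes for sensing short-chain fatty acids were among those fixed in advance. The receptors for acetate and propionate, Ffar2 and Ffar3, had log2 fold changes of -0.37 (SE 0.13, adjusted p = 0.0414) and -0.52 (SE 0.16, adjusted p = 0.0213), and with library totals these turned to 0.34 and 0.19. Hcar2, a receptor for ketone bodies, niacin and butyrate, had -0.60 (adjusted p = 0.00826), turning to 0.10. Dnmt1, the maintenance DNA methyltransferase, had -0.37 (adjusted p = 0.0448, with totals 0.32), and Dnmt3a, which methylates unmethylated DNA, had -0.32 (adjusted p = 0.0401, with totals 0.38). Ren1, which encodes renin, had -0.50 (adjusted p = 0.0167, with totals 0.20) and Tgfb1, a cytokine of fibrosis, -0.41 (adjusted p = 0.0436, with totals 0.28). Cyclic loess ended the calls of Ffar2 (-0.14), Ffar3 (-0.32), Dnmt1 (-0.15), Dnmt3a (-0.05), Ren1 (-0.30) and Tgfb1 (-0.18), and 1 surrogate variable (-0.33 to -0.08) or the enrichment covariate (-0.43 to -0.15) ended these and that of Hcar2. Not past the threshold were Slc16a1 (0.43), Acss2 (0.04), Tet2 (0.31, with loess -0.20), Hdac4 (0.00) and Agtr1a (0.03, with loess -0.03), which library totals moved past it at 1.12, 0.74, 0.97, 0.70 and 0.73. Hdac4 also passed with loess (0.27, adjusted p = 0.0275). Egr1 (-0.38), Foxp3 (-0.14, with loess 0.02) and Nppa (-0.36) did not pass and turned to 0.32, 0.55 and 0.34 with totals, where Foxp3 passed (adjusted p = 0.0112).

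By gene list, captured DNA in high fibre heart was lower over germline genes, which act in egg and sperm formation, with 16 members lower and 1 higher of 44 (camera adjusted p = 0.000266), and 18 called adjusted over the list alone. The adjusted p was 0.43 with an estimated correlation. Of all tested windows 26.2% were called, the share to set beside the member counts, and the Hox count below lies under it. Sycp3 of the synaptonemal complex (-0.70), Fkbp6 (-0.66), Mei1 (-0.54) and Tex19.1 (-0.55) led it, and with library totals these turned to 0.01, 0.05, 0.15 and 0.16. Their calls held with cyclic loess and ended with 1 surrogate variable (-0.30 to -0.17) and with the enrichment covariate (-0.43 to -0.27). The germline genes are also part of the enrichment measure, which was 1.02 in high fibre and 1.17 in control heart. Hox cluster genes, the patterning genes of the body axis, were higher, with 6 members higher and 0 lower of 27 (adjusted p = 0.00145; 6 adjusted over the list alone). Their adjusted p was 0.43 with an estimated correlation, and Hoxb9 (1.58), Hoxd10 (1.38), Hoxc13 (1.23) and Hoxa10 (0.68) led at 1.45 to 5.19 CPM in control heart. These 4 lost their calls with cyclic loess (0.85, 0.64, 0.48 and 0.30), with the enrichment covariate (1.06, 0.36, 0.72 and 0.49) and with 1 surrogate variable, where Hoxd10 turned to -0.20. Histone acetylation genes were lower in 11 of 30 and higher in 0 (adjusted p = 0.0065; 13 adjusted over the list alone; adjusted p = 0.43 with an estimated correlation). The deacetylases Sirt2 (-0.80) and Sirt4 (-0.84) lost their calls with library totals (-0.10 and -0.13), and the acetyltransferase Kat5 (-0.63) and the deacetylase Hdac1 (-0.36) turned to 0.08 and 0.34. With 1 surrogate variable Sirt4, Kat5 and Hdac1 lost their calls, with the enrichment covariate Kat5 (-0.37) and Hdac1 (-0.27), and with loess Hdac1.

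Immune lists also passed camera with the preset correlation, in the same libraries of low Gm10800 share (19.05% against 42.3%). With cyclic loess 0 lists passed. Of all tested windows 26.2% were called, and the count of the regulatory and helper T cell list below lies under that share. Myeloid genes were lower in 10 and higher in 3 of 32 (adjusted p = 0.0160; 14 adjusted over the list alone; adjusted p = 0.33 with an estimated correlation). C1qa of complement (-0.54), Coro1a, an actin regulator (-0.60), Siglec1 of macrophages (-0.58) and Spi1, the myeloid transcription factor PU.1 (-0.55), turned to values between 0.10 and 0.16 with library totals. MHC and interferon response genes were lower in 11 and higher in 2 of 33 (adjusted p = 0.0169; 15 adjusted over the list alone; adjusted p = 0.43 with an estimated correlation). The antigen processing genes Tap1 (-0.61), Psmb8 (-0.50) and the interferon factor Irf9 (-0.64) turned to 0.09, 0.21 and 0.07 with totals, and Tapbp (-0.81) to -0.11. Regulatory and helper T cell genes were lower in 8 and higher in 0 of 35 (adjusted p = 0.0388; 8 adjusted over the list alone; adjusted p = 0.33 with an estimated correlation). Ikzf4 (-0.91) of regulatory T cells lost its call at -0.19 with totals, and the signal transducers Stat3 (-0.43) and Stat6 (-0.47) and the receptor Tnfrsf4 (-0.47) turned to 0.26, 0.23 and 0.23. All 12 genes named in this paragraph lost their calls with 1 surrogate variable (values of -0.43 to -0.18) and with the enrichment covariate (-0.60 to -0.29, Psmb8 at -0.42), and Stat3, Stat6 and Tnfrsf4 also with loess.

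The other lists did not pass in high fibre heart. DNA methylation and one-carbon genes had 1 higher and 11 lower of 34 (adjusted p = 0.0712; 14 adjusted over the list alone), T and NK cell genes 3 and 7 of 30 (0.0849; 12), cardiac stress, fibrosis and inflammation genes 3 and 7 of 38 (0.148; 15), B cell genes 3 and 5 of 25 (0.199; 8), and smooth muscle and pericyte genes 0 and 2 of 15 (0.199; 0). Cardiomyocyte genes had 3 higher and 7 lower of 41 (adjusted p = 0.272; 10), circadian clock genes 0 and 3 of 23 (0.279; 1), endothelial genes 1 and 2 of 21 (0.336; 2), and genes of short-chain fatty acid sensing, transport and acetate metabolism 5 and 13 of 36 (0.380; 21). Blood pressure and renin-angiotensin genes had 3 higher and 10 lower of 37 (0.544; 13), with a median log2 fold change of 0.01 although camera gave a downward direction. Fibroblast genes had 5 and 3 of 20 (0.598; 14), erythroid genes 3 and 5 of 17 (0.598; 8), imprinted genes 4 and 1 of 38 (0.794; 5), and housekeeping genes 3 and 6 of 29 (0.824; 10).

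Direction followed abundance. From the least abundant 10% of windows to the most abundant 10% the median log2 fold change went from 0.62 to -0.27 on high fibre against control, from 0.14 to 0.00 on acetate against control, and from 0.47 to -0.26 on high fibre against acetate. Among the least abundant 10% 642 windows were called higher and 20 lower on high fibre, and among the most abundant 10% 133 and 1415.

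**Figure D2:**
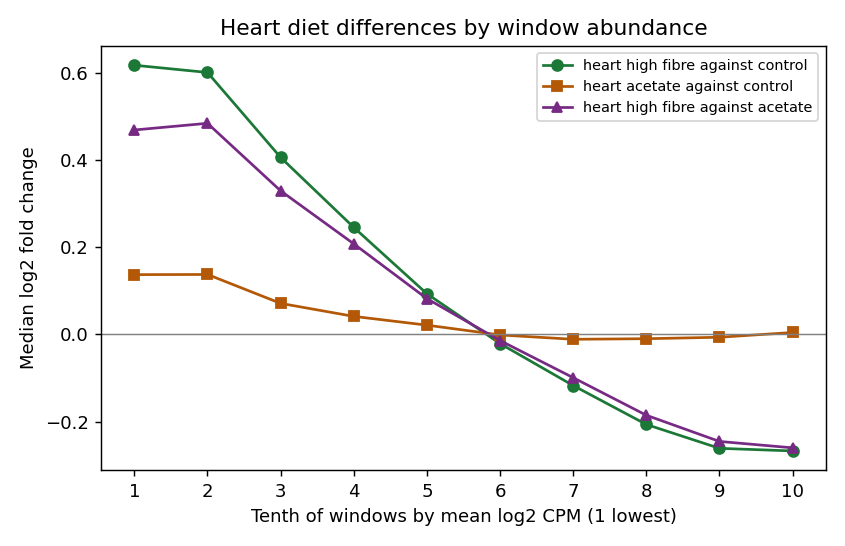
Median log2 fold change of the windows in 10 classes of mean abundance (log2 CPM) for the 3 heart comparisons. High fibre against control goes from 0.62 in the lowest class to -0.27 in the highest, directions that hold on the TMM scale, while library totals raise the median of all windows by over 0.1, to 0.71.

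Library totals moved the median of all windows from 0.02 to 0.71 and gave 24612 higher and 14 lower windows. Cyclic loess, which removes trends with abundance, called 5765 windows, 3793 of them among the 8786, and 0 lists. With 1 surrogate variable 109 windows were called, 95 of them among the 8786. The count was 2495 without control replicate 1, 2592 without high fibre replicate 4, 4707 without control replicate 3, 5174 and 5679 without high fibre replicates 3 and 2, and 14336 without acetate replicate 1.

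The second comparison asks the same of acetate in the heart. Tbc1d2b (ENSMUSG00000037410), a regulator of Rab proteins in membrane traffic, had 48.45 ± 9.31 CPM on acetate (n = 3) and 77.9 ± 10.8 on control (n = 4), a log2 fold change of -0.69 (SE 0.18, adjusted p = 1.00). Irx2, a heart and limb transcription factor, had 11.2 ± 1.72 and 6.32 ± 1.32 CPM (0.83, adjusted p = 1.00). The cell adhesion gene Itgb8 had 0.88, the polarity gene Lin7c 0.98, Olfr958 0.55 and Msl3l2 0.61, and on the lower side Eif3l, a translation factor subunit, had -0.50, Omt2a -0.61, Lrrn4cl -0.64 and Bpifb2 -0.50. None of these 10 passed the edgeR threshold. Among the fixed genes values lay near 0: Ffar2 0.07, Ffar3 -0.08, Hcar2 -0.06, Slc16a1 0.02, Acss2 -0.03, Dnmt3a 0.02, Tet2 -0.08, Hdac4 0.06, Egr1 0.13, Foxp3 -0.10, Nppa -0.24, Agtr1a -0.08, Ren1 0.02 and Tgfb1 -0.11, with Dnmt1 at 37.0 ± 6.92 CPM against 36.6 ± 2.38. All had an adjusted p of 1.00.

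By edgeR 0 of 33562 windows were called on acetate in heart, with 840 at an unadjusted p under 0.05, and DESeq2 and voom called 0. Of the 20 gene lists 0 passed, the smallest adjusted p being 0.561. Without acetate replicate 1, the library with the lowest median count (26) and the highest enrichment measure (1.42) in heart, 684 windows were called, 259 higher and 425 lower. In data with planted changes the same fit recovered 34.3% of windows changed 1.5-fold and 71.6% of those changed 2-fold. Those windows were drawn independently, so these rates need not hold where libraries differ as a whole. Library totals moved the median of all windows to 0.27.

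High fibre was also set against acetate in the heart, which asks whether fibre has effects beyond those of acetate. Captured DNA was lower on high fibre at Ehmt2 (49.1 ± 4.62 CPM, n = 4, against 91.3 ± 34.5, n = 3), and at Celsr1, a planar polarity cadherin, at 23.7 ± 4.14 against 48.3 ± 19.98 CPM. Scarf1, a scavenger receptor of endothelium, had 9.66 ± 1.53 against 20.4 ± 7.67 CPM, and Ccr8, a chemokine receptor of T cells, 21.2 ± 1.02 against 35.0 ± 5.32 CPM. Higher on high fibre were Lix1 (22.1 ± 1.75 against 12.96 ± 1.93 CPM) and Kcna4, a potassium channel of the cardiac transient outward current (11.8 ± 1.46 against 4.63 ± 2.51 CPM). The share of counts in the top 1% of windows was 28.8% in the high fibre and 44.5% in the acetate libraries, and the enrichment measure 1.02 and 1.20.

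The test called 462 windows, 63 higher and 399 lower, with 9105 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0488. Ehmt2 had a log2 fold change of -0.88 (SE 0.16), Scarf1 -1.01, Celsr1 -0.99, Cacnb1, a calcium channel subunit, -0.78, Kat2b-ps -0.77, Nlgn2, a synaptic adhesion gene, -0.76, Tnrc18 -0.75, Hps6 -0.74, Ccr8 -0.71 and Rab2b -0.67. The higher genes were Ceacam11 (2.06), Vmn2r29 (1.82), Olfr701 (1.64), Kcna4 (1.24), Rbm46 (1.22), Sult1d1 (1.06), Olfr619 (1.05), Zkscan3 (1.04), Serpinb2 (0.86) and Lix1 (0.75). Of the fixed genes 0 passed: Ffar2 had -0.44, Ffar3 -0.45, Hcar2 -0.53, Dnmt1 -0.37, Dnmt3a -0.34, Egr1 -0.50, Ren1 -0.52, Tgfb1 -0.31, Slc16a1 0.41 and Tet2 0.39. Acss2 (0.08), Hdac4 (-0.06), Foxp3 (-0.03), Nppa (-0.13) and Agtr1a (0.11) lay nearer 0.

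Germline genes were lower as a list (0 higher and 1 lower of 44 over all windows, 18 adjusted over the list alone, camera adjusted p = 6.85e-06), led by Tex101 of sperm (-0.59). Tex19.1, Sycp3 and Spo11 had -0.53, -0.60 and -0.48. Hox genes were higher as a list (0 members of 27 called, 0 adjusted over the list alone, adjusted p = 0.000667), with Hoxc13 at 1.25, Hoxb9 at 1.04, Hoxd4 at 0.86 and Hoxa10 at 0.71. Histone acetylation genes were lower as a list (2 of 30, 7 adjusted over the list alone, adjusted p = 0.00609), with Sirt4 at -0.70 and Sirt2 at -0.66 called, and Kat5 at -0.60 and Hdac7 at -0.49 not. MHC and interferon genes were lower as a list (3 of 33, 7 adjusted over the list alone, adjusted p = 0.0343), through Tapbp (-0.84), Irf9 (-0.65) and Psmb8 (-0.56), while the class II gene H2-Aa had 0.52. All 4 of these lists had an adjusted p of 0.39 with an estimated correlation. Library totals moved the median of all windows to 0.45 and gave 1875 higher and 7 lower windows, RLE, voom, cyclic loess and the fit to both diets alone gave 0, and DESeq2 gave 2516. The replicate block gave 2284, voom with quality weights 142, 1 surrogate variable 20 and the enrichment covariate 5. The count was 0 without high fibre replicate 1, 2 or 3, 4 without high fibre replicate 4, 98 without acetate replicate 1, 2951 without acetate replicate 2 and 4536 without acetate replicate 3.

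In the spleen, high fibre was compared with control to ask for an effect in an immune organ. The genes with the smallest p were Zc3h12d, a regulator of inflammatory transcripts, at 12.01 ± 1.02 CPM on high fibre and 7.72 ± 0.828 on control (n = 4 each, 0.63, adjusted p = 1.00), and Tgm4, a transglutaminase, at 8.63 ± 0.801 and 12.7 ± 1.29 CPM (-0.56). Next were the stem cell RNA-binding gene Msi1 (0.43), the carbonic anhydrase Car7 (0.42), Il27ra, the interleukin 27 receptor (0.56), Nfatc2ip (-0.43), Wnk1, a kinase of salt transport (-0.46), Birc5, the mitotic gene survivin (-0.91), and Sbf2 (-0.38). Among the fixed genes Ffar2 had -0.02, Ffar3 0.00, Hcar2 0.01, Acss2 0.01, Dnmt3a 0.01, Hdac4 -0.02, Egr1 0.22, Foxp3 0.05, Nppa 0.41, Agtr1a -0.21, Ren1 -0.09 and Tgfb1 -0.05, with Dnmt1 at 19.8 ± 2.07 against 19.8 ± 1.49 CPM. Slc16a1 and Tet2, at mean counts of 4.33 and 4.67, were not tested in spleen. By edgeR 0 of 24871 windows were called (502 at an unadjusted p under 0.05, DESeq2 0, voom 0), and 0 of the 20 lists, with a smallest adjusted p of 0.5002 for Hox genes. Planted 2-fold changes were recovered in 59.7% of independently simulated windows.

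In the spleen on acetate, Tbc1d2b again had the smallest p: 21.04 ± 4.13 CPM on acetate against 42.6 ± 2.61 on control (n = 4 each), with all acetate libraries below all control libraries. Its log2 fold change was -1.01 (SE 0.18), and its adjusted p of 0.191 did not pass. Mtmr2, a lipid phosphatase of nerve, had 0.65, the muscle gene Csrp3 0.98, the stress gene Ddit4 1.61 and RP23-145J9.11 1.98. Lower were Pet2 (-0.52), RP24-85N11.1 (-0.66), Pou3f3os (-0.39) and Prx, a myelin gene (-0.44), each with an adjusted p of 0.999. Foxp3, the factor of regulatory T cells, had 6.86 ± 1.01 against 8.94 ± 0.978 CPM (-0.37, adjusted p = 0.999) and Nppa, a natriuretic peptide, 0.58. Ffar2 had -0.08, Ffar3 0.03, Hcar2 -0.10, Acss2 0.04, Dnmt1 0.08, Dnmt3a 0.00, Hdac4 -0.02, Egr1 0.02, Agtr1a 0.46, Ren1 0.07 and Tgfb1 -0.06. By edgeR 0 of 24871 windows were called (872 at an unadjusted p under 0.05, voom 0), and 0 lists, with a smallest adjusted p of 0.757. DESeq2 called 1 window, Tbc1d2b (adjusted p = 0.0216), whose adjusted p over all alternatives ranged from 1.53e-06 to 1.00, and edgeR called 1 without control replicate 1. Library totals moved the median of all windows to 0.17.

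Tbc1d2b lies on chromosome 9 from 90202047 to 90270772, and its neighbours Gm22717 (90315910 to 90316080) and Gm22866 (90351995 to 90352171) went with it. On its other side Adamts7 (90162904 to 90200102) was not halved: it had 69.04 to 122 CPM on acetate and 78.6 to 92.97 on control in heart, and 58.3 to 84.4 and 64.6 to 99.2 in spleen. The sum of the CPM of these 3 windows was 126 ± 16.5 on control, 108 ± 30.9 on high fibre and 72.0 ± 8.13 on acetate in heart (n = 4, 4 and 3). In spleen it was 77.7 ± 4.84, 71.6 ± 22.5 and 37.9 ± 5.80 (n = 4 each). High fibre replicate 4, number 16 in both tissues, stood as low as acetate at 62.0 in heart and 39.3 in spleen. The neighbours and the sum were chosen after their values were seen.

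**Figure D3:**
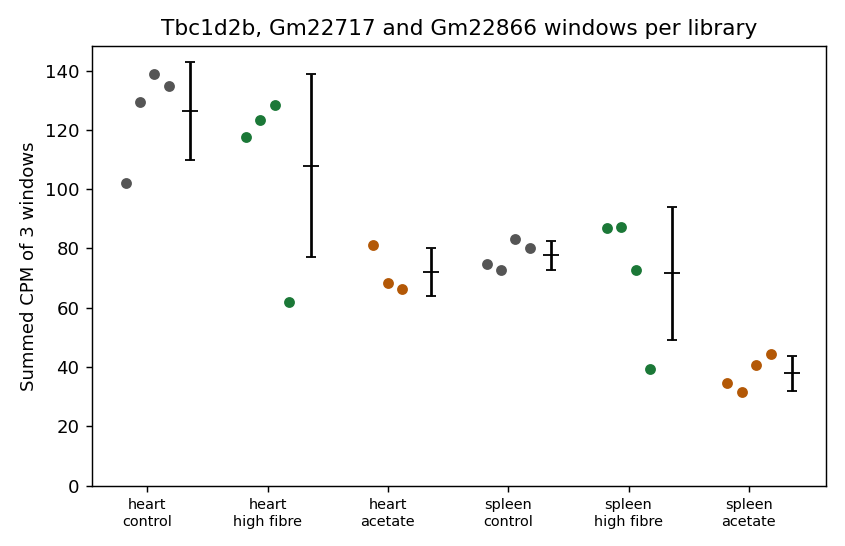
Summed CPM of Tbc1d2b, Gm22717 and Gm22866 in each library by tissue and diet, with group mean ± SD. Acetate libraries lie at 66.3 to 81.3 in heart and 31.6 to 44.5 in spleen, and high fibre replicate 4 at 62.0 and 39.3.

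Between high fibre and acetate in the spleen, Tbc1d2b had 39.6 ± 12.9 against 21.04 ± 4.13 CPM (0.90, SE 0.18, adjusted p = 0.501) and Wnk1 16.9 ± 2.98 against 27.7 ± 4.08 CPM (-0.72, SE 0.14, adjusted p = 0.501). Other genes with small p were Olfr761 (0.82), Pou3f3os (0.42), RP24-499N24.3 (0.43), Tcf20, a chromatin regulator (0.52), the mediator subunit Med6 (-0.55), Mib1, a ligase of Notch signalling (-1.64), the growth factor Egf (-0.83) and the nuclear matrix gene Matr3 (-1.55). Among the fixed genes Foxp3 had 0.42, Agtr1a -0.67, Egr1 0.20, Nppa -0.17, Ren1 -0.16, Hcar2 0.11, Dnmt1 -0.08, Ffar2 0.06, Ffar3 -0.03, Acss2 -0.03 and Tgfb1 0.01, and Dnmt3a and Hdac4 had 0.00 and -0.00. By edgeR 0 of 24871 windows were called (823 at an unadjusted p under 0.05, DESeq2 0, voom 0), and 0 lists (smallest adjusted p 0.679). The enrichment measure was 1.79 ± 0.05 on high fibre and 1.63 ± 0.06 on acetate (exact permutation p = 0.0286), and edgeR called 3 windows without high fibre replicate 4. Library totals moved the median of all windows to -0.17.

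Both diets were compared with the same controls, so their effects share the error of those controls. Across 33562 heart windows the effects of high fibre and acetate had a Pearson r of 0.21, against 0.46 in simulations without any change, and a covariance of 0.0227 against 0.0235. The heart r was 0.82 without acetate replicate 1, -0.20 without acetate replicate 2 and -0.23 without acetate replicate 3. In spleen r was 0.44 over 24871 windows, against 0.48 simulated, with a covariance of 0.0239 against 0.0288, and 0.29 without high fibre replicate 3. Windows are not independent replicates. With all libraries neither tissue had a covariance above the simulated one, and the covariance with a library left out was not computed. The simulations drew each window independently, without differences shared across the windows of a library. They therefore cannot decide whether the 2 diets share a direction.

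Heart and spleen on the control diet were compared to see what tissue differences the assay detects. Gfi1 (ENSMUSG00000029275), a transcriptional repressor of blood cells, had 58.9 ± 19.8 CPM in spleen and 1.07 ± 0.284 in heart (n = 4 each, 55.2-fold). Hoxa5 (ENSMUSG00000038253), a patterning gene, had 71.4 ± 15.5 in spleen and 1.86 ± 0.561 in heart. Runx3, a factor of T cell fate, had 64.1 ± 20.7 and 7.35 ± 0.570. In the other direction Rhoh (ENSMUSG00000029204), a signalling gene of lymphocytes, had 14.9 ± 0.731 CPM in heart and 0.852 ± 0.328 in spleen (16.3-fold), Plek of platelets and leukocytes 13.8 ± 2.27 and 1.37 ± 0.305, and Tnfsf14, a T cell ligand, 16.7 ± 0.774 and 1.99 ± 0.569. The heart muscle genes Mybpc3 and Myh6 had less captured DNA in heart, at 13.04 ± 1.79 against 68.9 ± 24.6 and 19.9 ± 3.07 against 66.0 ± 10.6 CPM.

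**Figure D4:**
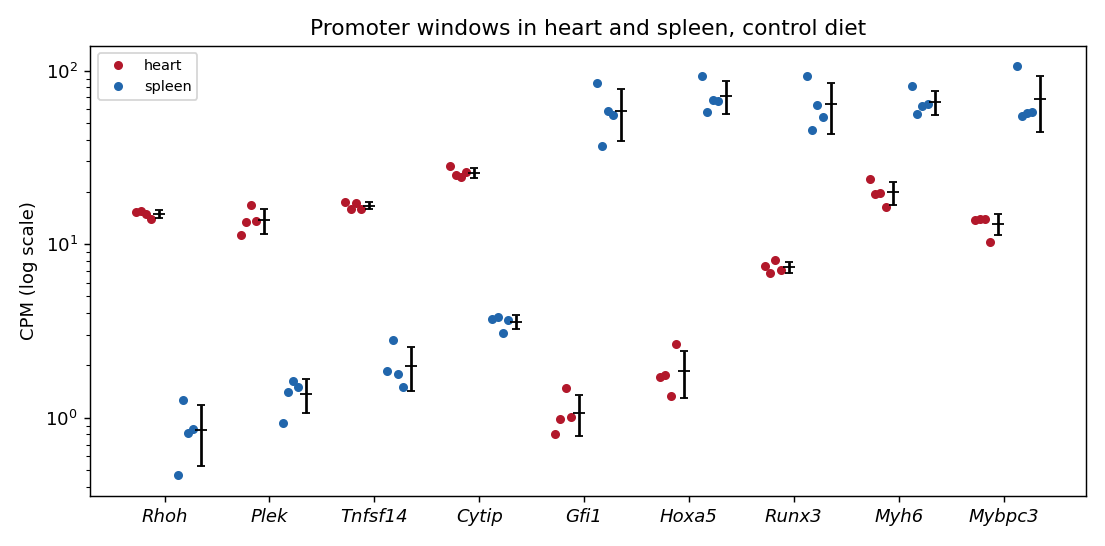
CPM on a log axis of 9 genes in 4 control heart and 4 control spleen libraries, with mean ± SD. Rhoh, Plek, Tnfsf14 and Cytip lie higher in heart, and Gfi1, Hoxa5, Runx3, Myh6 and Mybpc3 higher in spleen.

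Of 33982 windows 24708 (72.7%) differed between the tissues by edgeR, 13592 higher and 11116 lower in heart, with 25418 at an unadjusted p under 0.05. Rhoh had a log2 fold change of 4.03 (SE 0.26, adjusted p = 1.82e-14), Plek 3.28, Tnfsf14 3.00, and Cytip, a regulator of lymphocyte adhesion, 2.85. CR524822.1 (3.92), the RNA-binding gene Tia1 (3.00), the glycolipid anchor gene Pign (2.93), Gpbp1l1 (2.88), the transfer RNA modification gene Tyw5 (2.85) and the trafficking gene Dennd1a (2.81) were also higher in heart. Gfi1 had -5.79 (SE 0.31, adjusted p = 1.29e-16) and Hoxa5 -5.24 (SE 0.21, adjusted p = 6.31e-20). Lower in heart were also Agap2 (-4.66), Tenc1 (-4.26), Hoxaas2 (-3.49), the homeobox gene Gbx2 (-3.42), Hoxa4 (-3.24), Gcc1 (-3.24), Runx3 (-3.12) and Gimap1os (-3.11). In each of these genes the 4 heart and 4 spleen libraries did not overlap.

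Among gene lists, germline genes were lower in heart in 38 and higher in 3 of 44 (camera adjusted p = 7.04e-10; 41 adjusted over the list alone; adjusted p = 0.30 with an estimated correlation). They included Dppa3 of the early embryo (-2.00), Taf7l (-2.40), Taf9b (-1.83) and Mael (-1.85). These genes are part of the enrichment measure, which was 1.17 ± 0.09 in heart and 1.73 ± 0.14 in spleen. Cardiomyocyte genes were lower in heart in 24 and higher in 12 of 41 (adjusted p = 0.00983; 37 adjusted over the list alone; adjusted p = 0.30 with an estimated correlation), led by Mybpc3 (-2.39), Myh6 (-1.73), and Ankrd1 and the splicing gene Rbm20 (each -1.65). Circadian clock genes were lower in 17 and higher in 3 of 23 (adjusted p = 0.00207; 22 adjusted over the list alone; adjusted p = 0.30 with an estimated correlation), such as Nr1d1 (-1.95), Timeless (-1.64), Dbp (-1.43) and Cry2 (-1.31). Short-chain fatty acid genes were lower in 19 and higher in 9 of 36 (adjusted p = 0.0404; 28 adjusted over the list alone; adjusted p = 0.30 with an estimated correlation), among them Hcar1 (-1.57), Slc16a3 (-1.48), Ffar2 (-1.44) and Ffar3 (-1.40). Cardiac stress genes were lower in 19 and higher in 7 of 38 (26 adjusted over the list alone), with Tgfb3 (-1.61), Egr1 (-1.59) and the slow myosin gene Myh7 (-1.52) among them. Imprinted genes were lower in 20 and higher in 10 of 38 (30 adjusted over the list alone), such as Cdkn1c (-2.14), Mcts2 (-2.04), Ndn (-1.67) and Snrpn (-1.53). Both lists had an adjusted p of 0.0482, and adjusted p = 0.30 with an estimated correlation. Histone acetylation genes were lower in 16 and higher in 7 of 30 (adjusted p = 0.0482; 23 adjusted over the list alone; adjusted p = 0.51 with an estimated correlation). Sirt4 (-1.52) and Sirt5 (-1.50) were lower, and Hdac10 (2.32) and Crebbp (1.48) higher, in heart. Of the 47 genes named for the tissues, 14 lost their call with 1 surrogate variable and 15 with the enrichment covariate. Lost with both were Ffar2, Ffar3, Slc16a3, Sirt4, Sirt5, Egr1, Nr1d1, Timeless, Dbp, Cdkn1c, Mael, Myh6 and Gpbp1l1, with the surrogate variable alone Pign, with the covariate alone Mybpc3 and Taf7l, and with library totals Cry2, and each kept its sign.

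The remaining lists did not pass between the tissues, among them B cell (16 higher and 4 lower of 25, adjusted p = 0.0685), DNA methylation and one-carbon (10 and 19 of 35, 0.130), smooth muscle and pericyte (3 and 8 of 15, 0.148) and Hox (5 and 9 of 29, 0.148). With cyclic loess, germline, Hox, B cell, T and NK cell, cardiomyocyte, regulatory and helper T cell and myeloid lists passed, the circadian, short-chain fatty acid, cardiac stress and imprinted lists did not, and histone acetylation turned upward (adjusted p = 0.320). TMM left the median of all windows at 0.20, RLE put it at 0.32, loess at 0.04 and library totals at 1.10 with 23371 higher and 2067 lower windows, and with the added enrichment covariate 2872 windows were called, 2710 of them among the 24708.

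Whether the high fibre effect differed between heart and spleen was tested directly. At Wnk1 (ENSMUSG00000045962), a kinase that controls salt transport and blood pressure, captured DNA went from 47.6 ± 3.26 to 73.6 ± 5.26 CPM on high fibre in heart (0.64), against -0.46 in spleen, a difference of 1.09 (SE 0.20, adjusted p = 0.0202). Il27ra had -0.76 in heart and 0.56 in spleen (difference -1.31, adjusted p = 0.0439). Trps1, a repressor of bone and hair development, had 0.52 and -0.72 (difference 1.26), and Hs3st5, a heparan sulfate enzyme, 1.02 and -1.33 (difference 2.38). The spleen values alone did not pass the threshold.

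In all 19 windows differed, 6 higher and 13 lower, with 5571 at an unadjusted p under 0.05, and DESeq2 gave 110, voom 17, the replicate block 980, voom with quality weights 2098 and the enrichment covariate 6. The others with a printable name were Hook1 (0.93), Olfr309 (1.88), Ear14 (2.77), Msi1 (-0.96), Hps6 (-0.93) and Lrrc43 (-1.04). In heart alone Ear14 had only 0.10 (edgeR adjusted p = 0.668), and it was not tested in spleen alone for want of reads. Germline (adjusted p = 0.0206), histone acetylation, regulatory and helper T cell (each 0.0361) and Hox genes (0.0361) passed as lists, with 0 single members called over all windows. Adjusted over the list alone, 1 regulatory and helper T cell gene was called and 0 in the other lists. With an estimated correlation the adjusted p = 0.54 for germline and histone acetylation, adjusted p = 0.34 for regulatory and helper T cell and adjusted p = 0.51 for Hox genes. Their leading members had Ikzf4 -1.12, Tbx21 -0.79, Stat6 -0.49, Stat3 -0.45, Sirt4 -0.75, Sirt2 -0.70, Hdac6 -0.63, Hdac3 -0.53, Fkbp6 -0.86, Dppa3 -0.56, Mei1 -0.49, Nlrp14 0.66, Hoxd10 3.79, Hoxc9 2.17, Hoxb9 1.43 and Hoxb6 0.87. The Gm10800 share differed in the same direction between tissues (-23.1 points), library totals moved the median of all windows to 0.66 with 6380 higher and 8 lower windows, and loess gave 61 and 42. Leaving out 1 library gave 602 windows without spleen control replicate 1, 9 without heart control 4 or spleen high fibre 3, 7 without spleen high fibre 2, and 6 without heart control 2, heart high fibre 1 or spleen high fibre 1. It gave 5 without heart high fibre 3 or spleen high fibre 4, 1 without heart control 1, spleen control 3 or spleen control 4, and 0 without heart control 3, heart high fibre 2, heart high fibre 4 or spleen control 2.

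For acetate, 0 of 33982 windows differed in effect between the tissues by edgeR, with 1553 at an unadjusted p under 0.05, and DESeq2 and voom gave 0. The smallest p was at Fbxw24, an F-box gene (-4.32, SE 0.86, adjusted p = 0.415), with between 0 and 58 reads per library. Hs3st5 had 1.70, Cybb, the phagocyte oxidase, 1.00, Cst12 0.75, Pou3f3os 0.60, RP23-293C19.2 2.52, Slc22a19, a transporter, -3.55, Pigg -2.50, Parp12 -2.13 and RP23-145J9.11 -2.05. Of the 20 lists 0 passed, the smallest adjusted p being 0.586. Planted 2-fold differences were recovered in 29.9% of independently simulated windows.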

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

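The tests of the enrichment covariate, of the Gm10800 share and of the Tbc1d2b region were chosen after their results or the pattern had been seen. The thinning test and the test against heart acetate replicate 1 were set out after the pattern was seen but before their own results. The splits of the libraries were set out before.

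High fibre heart differed from control heart at 8786 windows, and the median change fell with abundance, from 0.62 among the least abundant 10% of windows to -0.27 among the most abundant 10%. Unequal depth is argued against as the cause: after thinning all heart libraries to 2.41 M reads outside the 5 largest windows, 6031 windows were called, among them 5728 of the 8786. A candidate explanation is lower capture of methyl-CpG DNA in the high fibre libraries: across 33562 windows the high fibre effect had a Spearman rho of -0.799 (from -0.839 to -0.586 within 10 classes of abundance) with the difference of heart acetate replicate 1, the library of highest enrichment, from acetate replicates 2 and 3. With the enrichment measure as a covariate 331 of the 8786 windows were called again, but the measure parts the diets (at most 1.06 on high fibre, at least 1.07 on control), so an effect of the diet on methylation and an effect of enrichment cannot be told apart with it. An effect of the diet therefore stays open beside a difference in capture, as do the causes of the capture difference itself, for which the labels give no batch.

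Reads over Tbc1d2b, Gm22717 and Gm22866, but not over Adamts7 next to Tbc1d2b, were about halved on acetate in both tissues at the level of groups. Single libraries overlapped at Gm22717. Heart acetate replicate 2 had 14.5 CPM and control replicate 1 14.0, and spleen acetate replicate 1 had 9.78 and control replicate 1 9.47. Acetate as the whole cause is argued against by 2 of 16 libraries of other diets, high fibre replicate 4 in heart (62.0 summed CPM) and in spleen (39.3), both number 16, which lay as low as the highest acetate library of their tissue (81.3 and 44.5). A difference carried by single animals stays open: 23 pairs of window and number deviated alike in heart and spleen over 13606 windows, but 6 of them are Tbc1d2b and Gm22866 themselves, which prompted the test. Exchanging the spleen numbers within diets gave 8 to 23 pairs with a median of 14, and 1 of 100 exchanges reached 23, so the set criterion of more than any exchange was not met. Every exchange kept the Gm22866 pairs of the acetate libraries and could leave other numbers with their own partner, so the criterion cannot decide the question. The median ratio of acetate to control was 0.503 (0.443 to 0.622 over 6 values), near that of a lost gene copy. A change in methylation has no fixed ratio and no input library was used, so copy number and methylation cannot be told apart. Every library with a title number from 11 was low (62.0 to 81.3 summed CPM in heart, 31.6 to 44.5 in spleen). Every library numbered 1 to 8 was higher (102 to 139 and 72.6 to 87.2). All acetate libraries have such later numbers. An effect of acetate in them and a difference tied to the number series cannot be told apart, and both stay open.

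Other splits of the same libraries show how the real count ranks where windows were called. For high fibre against control in heart the real split called 8786 windows and the highest of the other splits 8. It was the only 1 of 35 splits with as many, the smallest share that 35 splits allow. The real split also ranked first for high fibre against acetate in heart (462 against 1, 1 of 35) and for heart against spleen (24708 against 0, 1 of 35). The same rank was found for the tissue difference in the high fibre effect (19 against 11, 1 of 100). Mixed splits put a real difference into the spread within groups, which can lower their calls. These ranks were not adjusted over the comparisons and make a chance split less likely without excluding it. Where 0 windows were called, every split gives as many by construction, so the splits do not test chance. This holds for heart acetate against control (0 called, 35 of 35 splits). There the highest other split called 4853, with control replicates 1 and 3 and acetate replicate 1 on one side, which points to a structure of the samples apart from diet. It also holds in spleen for high fibre against control, acetate against control and high fibre against acetate (0 called, 35 of 35 splits each), where the highest other splits gave 2, 5 and 2. The tissue difference in the acetate effect is such a case too (0 called, 100 of 100 splits), and its highest other split gave 1860, which again points to a structure of the samples. Leaving out single libraries moved these counts: in heart, high fibre against control gave 2495 and 4707 without control replicates 1 and 3, 5679, 5174 and 2592 without high fibre replicates 2, 3 and 4, and 14336 without acetate replicate 1. Heart acetate against control gave 684 without acetate replicate 1. High fibre against acetate in heart gave 0 without high fibre replicate 1, 2 or 3, 4 without replicate 4, and 98, 2951 and 4536 without acetate replicates 1, 2 and 3. In spleen, acetate against control gave 1 without control replicate 1, and high fibre against acetate 3 without high fibre replicate 4. The tissue difference in the high fibre effect gave 602 without spleen control replicate 1, 9 without heart control replicate 4 or spleen high fibre replicate 3, 7 without spleen high fibre replicate 2, and 6 without heart control replicate 2, heart high fibre replicate 1 or spleen high fibre replicate 1. It gave 5 without heart high fibre replicate 3 or spleen high fibre replicate 4, 1 without heart control replicate 1, spleen control replicate 3 or spleen control replicate 4, and 0 without heart control replicate 3, heart high fibre replicate 2, heart high fibre replicate 4 or spleen control replicate 2.

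The high fibre effect differed between heart and spleen, tested as the difference itself, at genes whose heart minus spleen difference on the log2 scale was 1.09 for Wnk1 (adjusted p = 0.0202) and -1.31 for Il27ra, -0.96 for Msi1, 0.93 for Hook1, -0.93 for Hps6, 1.26 for Trps1, 2.38 for Hs3st5 and -1.04 for Lrrc43 (adjusted p = 0.0439 each). Olfr309 (1.88) and Ear14 (2.77) had an adjusted p of 0.0479. Ear14 had only 0.10 in heart alone (edgeR adjusted p = 0.668) and was not tested in spleen alone for want of reads. For the share of counts in Gm10800 the difference was -23.1 points (permutation p = 0.0147), where the permutation tests for no diet effect in either tissue, not for equal effects. These gene counts rest on single libraries, as given above.

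Single libraries stood apart from the other 3 of their group in 42 of 684 groups tested, where chance gives about 1 in 20; the gap is given as a share of the group's range. In the share of counts in the top 1% of windows, spleen control replicate 2 had 63.2% against 68.2 to 69.1% (gap 0.839). Of its windows, spleen acetate replicate 3 had 21.7% without reads against 16.7 to 17.5% (gap 0.854), and Hs3st5 at 0 CPM against 1.12 to 1.34 (gap 0.833). In CPM, heart high fibre replicate 1 had Hps6 at 24.2 against 20.8 to 21.1 (gap 0.922), Cryaa at 19.6 against 16.7 to 16.97 (gap 0.894), Coro1a at 41.6 against 30.9 to 32.5 (gap 0.851), Tgfb3 at 17.98 against 12.8 to 13.7 (gap 0.836) and Tbx21 at 4.90 against 5.98 to 6.14 (gap 0.871). Heart high fibre replicate 4 had Ehmt2 at 41.8 against 50.9 to 51.6 (gap 0.931), Acss2 at 14.1 against 11.3 to 11.6 (gap 0.896), Spi1 at 39.3 against 43.9 to 44.6 (gap 0.870) and Tbc1d2b at 39.8 against 74.7 to 76.7 (gap 0.944). Heart high fibre replicate 3 had Rbm46 at 8.54 against 13.3 to 14.2 (gap 0.830) and Tnrc18 at 32.0 against 38.6 to 40.0 (gap 0.832), and replicate 2 had Hoxb6 at 4.88 against 5.70 to 5.83 (gap 0.857). Heart control replicate 1 had Rab2b at 32.7 against 29.3 to 29.7 (gap 0.867) and Hook1 at 30.8 against 37.7 to 38.8 (gap 0.863). Heart control replicate 4 had Mybpc3 at 15.6 against 20.9 to 21.2 (gap 0.952) and RP23-145J9.11 at 13.5 against 11.1 to 11.5 (gap 0.834).

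In spleen, high fibre replicate 1 had Hoxaas2 at 29.8 CPM against 26.7 to 26.9 (gap 0.959), Runx3 at 51.4 against 39.9 to 40.8 (gap 0.926), Rbm20 at 128 against 109 to 110 (gap 0.954) and Myh6 at 55.7 against 39.5 to 40.8 (gap 0.917). The same library had Sirt2 at 56.2 against 42.8 to 43.3 (gap 0.958), Hdac6 at 34.6 against 25.2 to 26.6 (gap 0.850), Ikzf4 at 19.9 against 15.99 to 16.6 (gap 0.846) and Hoxd10 at 0.246 against 0 in the others (gap 1). Spleen high fibre replicate 3 had RP23-145J9.11 at 2.41 against 0.626 to 0.786 (gap 0.910), Gpbp1l1 at 3.45 against 0.982 to 1.25 (gap 0.891), Fbxw24 at 1.72 against 0.393 to 0.491 (gap 0.926) and Parp12 at 3.28 against 0.524 to 0.939 (gap 0.849). Spleen control replicate 1 had RP24-85N11.1 at 7.45 against 8.64 to 8.88 (gap 0.831), Mybpc3 at 70.5 against 38.3 to 40.6 (gap 0.928), Mcts2 at 62.3 against 43.2 to 45.7 (gap 0.869) and Sirt2 at 68.0 against 42.5 to 46.2 (gap 0.854). Spleen control replicate 2 had Zc3h12d at 8.94 against 7.31 to 7.52 (gap 0.868), replicate 3 had Dnmt1 at 22.04 against 19.2 to 19.6 (gap 0.860) and Tgfb3 at 25.6 against 19.6 to 20.2 (gap 0.899), and replicate 4 had Hoxd10 at 0.903 against 0.295 to 0.332 (gap 0.938). Spleen acetate replicate 1 had Birc5 at 2.28 against 4.36 to 4.70 (gap 0.861), and replicate 4 had Sirt5 at 40.1 against 31.3 to 31.9 (gap 0.927) and Taf7l at 56.3 against 33.4 to 34.9 (gap 0.935).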

How the results depend on the processing

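The enrichment covariate, the covariate for title numbers from 11 and the heart fit without acetate replicate 1 were chosen after the data were seen; the other alternatives were set out before. The cause was not tested for any value given here unless stated. Of 6599 values of named genes under alternatives 5724 stayed on their side of the threshold, 283 of them with another sign but no call under either setting. Of the others 723 lost their call, 126 gained one and 26 reversed with a call under at least 1 of the settings. Values without a call under either setting count as staying. Of 60 values for high fibre against control in heart, 21 stayed with 1 surrogate variable, 30 with the enrichment covariate and 17 with library totals. With cyclic loess 44 stayed, with RLE or DESeq2 58 and with voom 60.

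Windows called for high fibre against control in heart (8786) were 24626 with library totals, 5765 with cyclic loess, 4591 with a covariate for title numbers from 16, 2650 with that from 11, 109 with 1 surrogate variable, 13984 with only the compared diets and 338 with the enrichment covariate. RLE (8522), DESeq2 (7868), voom (9790), voom with quality weights (13035) and the replicate block (10501) stayed within 1.5 times. Leaving out 1 library gave 2495 (control replicate 1) to 14336 (acetate replicate 1), with 4707 without control replicate 3 and 5679, 5174 and 2592 without high fibre replicates 2, 3 and 4.

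For heart acetate against control (0) the counts were 2 with loess, 1 with the block, 13 with quality weights, 17 with the surrogate variable, 1 with only the compared diets and 3 with the enrichment covariate, and 0 to 684 (without acetate replicate 1) with 1 library left out. For high fibre against acetate in heart (462) they were 0 with RLE, voom, loess and only the compared diets, 1882 with totals, 2516 with DESeq2, 1256 with no filter, 786 with a mean of 30 reads, 2284 with the block, 142 with quality weights, 3164 and 1 with title numbers from 16 and 11, 20 with the surrogate variable and 5 with the enrichment covariate. Leaving out 1 library gave 0 (high fibre replicate 1, 2 or 3) to 4536 (acetate replicate 3), with 4 without high fibre replicate 4, 98 without acetate replicate 1 and 2951 without acetate replicate 2.

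In spleen, high fibre against control (0) gave 1 with the surrogate variable and 0 to 0 with 1 library left out. Acetate against control (0) gave 1 with DESeq2, the block or quality weights, 2 with no filter or only the compared diets, 21 with the surrogate variable and 38 with the enrichment covariate, and 0 to 1 (without control replicate 1) with 1 library left out. Tbc1d2b there had adjusted p = 0.0216 with DESeq2, 0.00265 with no filter and 0.000213 with the enrichment covariate, over a range of 1.53e-06 to 1.00, and a log2 fold change of 0.02 with title numbers from 11, a covariate shared by all acetate libraries and high fibre replicate 4. High fibre against acetate (0) gave 1 with totals, no filter or quality weights, 7 with the surrogate variable and 364 with the enrichment covariate, and 0 to 3 (without high fibre replicate 4) with 1 library left out.

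Heart against spleen (24708) gave 15931 with a mean of 30 reads, where fewer windows are tested, 3682 with the surrogate variable and 2872 with the enrichment covariate, and 23034 to 24469 with 1 library left out. The tissue difference in the high fibre effect (19) gave 6388 with totals, 110 with DESeq2, 103 with loess, 980 with the block, 2098 with quality weights and 6 with the enrichment covariate, and 0 to 602 (without spleen control replicate 1) with 1 library left out. Of the other 15 libraries, leaving out 1 gave 9 without heart control replicate 4 or spleen high fibre replicate 3, 7 without spleen high fibre replicate 2, 6 without heart control replicate 2, heart high fibre replicate 1 or spleen high fibre replicate 1, and 5 without heart high fibre replicate 3 or spleen high fibre replicate 4. It gave 1 without heart control replicate 1, spleen control replicate 3 or spleen control replicate 4, and 0 without heart control replicate 3, heart high fibre replicate 2, heart high fibre replicate 4 or spleen control replicate 2. That for acetate gave 0 with every alternative fitted to it and every library left out.

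Gene lists past the threshold for high fibre against control in heart (6) fell to 0 with an estimated correlation and with loess. High fibre against acetate in heart (4) gave 0 with an estimated correlation, 2 with fry and 1 with loess, heart against spleen (7) gave 0 and 17 with fry, and the tissue difference for high fibre (4) gave 0, 1 with fry and 0 with loess.

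With library totals these log2 fold changes of high fibre against control in heart reversed, with a call on at least 1 of the scales: Aanat 0.0011, Ffar2 0.34, Ffar3 0.19, Hcar2 0.10, Dnmt1 0.32, Dnmt3a 0.38, Foxp3 0.55, Ren1 0.20, Tgfb1 0.28, C1qa 0.16, Coro1a 0.10, Siglec1 0.12, Spi1 0.15, Kat5 0.0756, Hdac1 0.34, Stat3 0.26, Stat6 0.23, Tnfrsf4 0.23, Sycp3 0.0132, Tex19.1 0.16, Fkbp6 0.0482, Mei1 0.15, Irf9 0.0676, Tap1 0.0884 and Psmb8 0.21. Egr1 and Nppa, called on neither scale, turned to 0.32 and 0.34. The shift of the median of all windows to 0.71 under that scale gives these signs by construction. Hoxd10 reversed to -0.20 with the surrogate variable. The total of counts in heart, -2.18 M for high fibre against control, was 0.0732 M over 29917 autosomal windows, since the 5 largest windows have no chromosome and drop out. The number of planned composition tests under p 0.05 (9) was 6 to 10 with 1 library left out.

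The correlation of both diet effects in heart (0.21) was -0.15, -0.28 and -0.12 when high fibre was set against control replicates 1 and 2, 1 and 3 or 1 and 4 and acetate against the other controls. With replicates 2 and 3, 2 and 4 or 3 and 4 for high fibre it was 0.23, 0.34 and 0.24, and it was -0.23 to 0.82 with 1 library left out (0.82, -0.20 and -0.23 without acetate replicates 1, 2 and 3). In spleen (0.44) it was 0.036, -0.019, 0.012, -0.20, -0.15 and 0.012 over the 6 splits of the controls, and 0.29 (without high fibre replicate 3) to 0.57 (without control replicate 2).

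Of planted 1.5-fold, 2-fold and 3-fold changes 52.2%, 76.1% and 92.4% were found for high fibre in heart, 29.9%, 59.7% and 86.4% for high fibre in spleen, and 2.99%, 28.4% and 71.2% for the tissue difference in the high fibre effect. The simulated windows were independent, so these rates need not hold where libraries differ as a whole.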

Other observations

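Immune genes that the tissue comparison did not name differed between control heart and spleen at the level of single genes; these members were picked after their values were seen. The B cell genes Cxcr5, a receptor that guides cells to follicles (21.4 CPM in heart against 4.93 in spleen, log2 fold change 2.04), Ms4a1, the gene of CD20 (11.2 against 2.76, 1.98), Bank1 (3.28), Pou2af1 (1.57) and Cd79b of the B cell receptor (1.35) had more captured DNA in heart. Of natural killer and T cell genes Klrb1c (10.1 against 0.914, 3.34), the protease gene Gzma (10.03 against 1.57, 2.67) and Cd2 (1.01) were higher in heart, and the signalling kinase gene Zap70 lower (-1.40). The costimulator Icos (2.97), the cytokine Il10 (13.2 against 3.39, 1.96) and Ikzf2 of regulatory T cells (3.24) were higher in heart, as were the myeloid genes Ctss (2.64), Mpeg1 (1.61) and Lyz2, the gene of lysozyme (1.42). Members of vessel lists went both ways: Aplnr (-2.46) and Sox18 (-2.18) of endothelium and Tagln (-1.94) and Abcc9 (-1.69) of smooth muscle were lower in heart, while Emcn (2.44) and Myh11 (1.85) were higher. T and NK cell (15 higher and 7 lower of 30, camera adjusted p = 0.296), myeloid (15 and 11 of 32, 0.565), regulatory and helper T cell (16 and 11 of 35, 0.643) and endothelial genes (6 and 10 of 21, 0.155) did not pass as lists. Nor did housekeeping (8 and 13 of 29, 0.296), fibroblast (6 and 7 of 20, 0.555), erythroid (4 and 6 of 18, 0.645), blood pressure and renin-angiotensin (15 and 13 of 37, 0.902) or MHC and interferon response genes (12 and 11 of 33, 0.902). Library totals put the median of all windows at 1.10 in this comparison and TMM at 0.20.

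In high fibre heart, further members of lists past or short of their threshold were called, again picked after their values were seen. Of heart muscle genes Pln, the brake of the calcium pump, rose from 2.55 to 7.15 CPM (1.51), Kcnj2, an inward rectifier potassium channel, by 1.21 and the factor Gata4 by 0.55, while Myl3 (-0.54) and the troponin gene Tnni3 (-0.60) were lower. Of one-carbon and methylation genes Gnmt (-0.75) and Uhrf1 (-0.60) were lower. The lactate carrier Slc5a12 was higher (0.89) and the lactate receptor Hcar1 lower (-0.63), and of vessel genes Sox17 was higher (1.04) and Nos3, the nitric oxide synthase of endothelium, lower (-0.57). The Gm10800 share of these libraries was 19.05% against 42.3%. Windows of low abundance rose as a class in this comparison, as given above, so a rise at a low CPM need not be particular to its gene. These values are on the TMM scale. Library totals put the median of all windows at 0.71, and the signs of these members under that scale were not computed. Nor were their values with cyclic loess, 1 surrogate variable or the enrichment covariate.

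Some windows other than those beside Tbc1d2b deviated alike in heart and spleen libraries of the same title number, given as log2 deviations in heart and spleen. Tmem181b-ps on chromosome 17 had -1.05 and -1.07 at number 4 and -0.97 and -0.85 at number 17. On chromosome 13, 4833420G17Rik had -1.60 and -1.15 at number 3. Gm15726 had 1.74 and 2.04 at number 4, and -1.74 and -1.54 at number 16. Exchanging the spleen numbers within diets gave 8 to 23 such pairs with a median of 14, against 23 with own numbers. An exchange could leave some numbers with their own partner, so these counts do not show how many pairs arise without a shared number.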
